A study of Danio rerio with 16 samples.

How the data were processed

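Per the labels, RNA came from pools of 9 whole embryos, 1 pool per dish, of the Tropical 5D wild type and a wfikkn1 mutant line, exposed for 1 h at 4 hpf to 1 ng/mL TCDD or 0.1% DMSO and collected at 48 hpf. Per the labels, RNA with an integrity number above 8 was made into stranded, poly(A)-selected libraries and sequenced in 6 lanes as single-end reads of 100 bp. The labels list 16 samples in 4 groups, and the count table held 14 columns; replicate 2 of both wild-type groups was not used here.

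The count values are raw read counts per gene that the authors made; the authors name cutadapt 1.8.1, HISAT2 2.2.0, SAMtools 1.10, HTSeq 0.12.4 and edgeR (no version) and assembly GRCz11, without an annotation release or a strand setting. The authors' deposited tables of 4 comparisons hold log2 ratios and log2 mean CPM computed by the authors, listed only for genes past their threshold. The p-value and FDR columns in those tables are, per the file headers, those of the authors' edgeR quasi-likelihood test, and its F statistic is a score the authors deposited beside them. The authors' tables were used for gene names and for a comparison with the calls made here, and all other values were computed from the counts.

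Total counts per library ran from 20597475 to 26884477, the 10 most abundant genes took 9.85% to 11.7% of them, and TMM factors ran from 0.97 to 1.02. Of 32520 genes, 20098 passed edgeR's filterByExpr and 12422 were not tested. Counts were fitted in R 4.3.3 with edgeR 4.0.16 (TMM scaling, quasi-likelihood F tests, 1 mean per group over all 14 libraries) for TCDD against DMSO in each line, mutant against wild type in each exposure, and the difference of the TCDD effects. p was adjusted by Benjamini and Hochberg and called under 0.05; SE is the log2 fold change over the square root of F. The biological coefficient of variation was 0.151. CPM is scaled by TMM, and the floor is 3 counts per library.

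Gene names came from the authors' tables (10902 IDs) and otherwise from a table of gene names (18822), and 2796 IDs had none. Chromosomes came from assembly GRCz12tu, which is not the assembly of the counts, and served only to place genes. The 32 gene lists included the AHR battery, AHR receptors and partners, NRF2 and glutathione (oxidative stress), cartilage, bone, fast, slow and cardiac muscle, myogenic regulators, TGF-beta with activin and myostatin, matrix and fin fold, lens, photoreceptor, neuron, glia, pigment cell, epidermis, vascular, erythroid, leukocyte, liver and yolk syncytium, exocrine pancreas, hatching gland, cell cycle, heat shock, circadian, hypoxia and glycolysis, sterol synthesis, retinoid and steroid metabolism, mitochondrially encoded and ribosomal protein genes. They were tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over the 32 lists), and again with an estimated correlation and with fry.

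The comparisons, lists, alternatives and the rule for named genes were chosen before the data were examined. Named were wfikkn1, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1, no overlap between the groups and a name that is not a clone or locus, all AHR battery genes, up to 4 called members of smallest adjusted p per list, and for the difference the 10 smallest adjusted p, ties taken by unadjusted p. Members of other lists named for the difference were chosen after their values were seen. Some genes under this rule, and 1 of the lists, are not reported here.

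The within-group axis is the first singular vector of log2 CPM (prior count 2) after subtraction of group means. Each library's score is the projection of its log2 CPM on that axis, without subtraction of group means, so that it keeps group differences. Principal components used the 500 most variable genes. Alternatives were RLE scaling, no filter, a filter of CPM of at least 1 in 4 libraries, DESeq2 1.42.0, limma-voom, only the groups compared, the replicate number as a block, lower against higher sample numbers as a term, a 2-fold threshold and each library left out in turn. The fit was tested on simulated data with 200 changed genes: 32.8% to 47.8% of 1.5-fold, 73.1% to 83.6% of 2-fold and 93.9% to 100% of 4-fold changes were recovered in the pairwise comparisons, 11.9%, 44.8% and 86.4% for the difference, and 4 to 10 unchanged genes were called. Simulated genes varied independently of each other, without the within-group axis, so these rates need not hold for the measured libraries. Length and GC content of genes were not analysed here.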

Results

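RNA was measured by sequencing in whole zebrafish embryos of 2 lines at 48 hours post fertilization (hpf). The lines were the Tropical 5D wild type and a line with a mutation in wfikkn1, a gene for a secreted protein with follistatin, Kunitz and netrin domains that is known to bind myostatin and GDF11. Embryos of each line were exposed for 1 h at 4 hpf to TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin, a ligand of the aryl hydrocarbon receptor, AHR) at 1 ng/mL or to 0.1% DMSO, the vehicle. The labels list 16 samples, each a pool of 9 embryos from its own dish. The count table held 14 of them, so that n = 3 for wild-type DMSO, n = 3 for wild-type TCDD, n = 4 for mutant DMSO and n = 4 for mutant TCDD. Replicate 2 of both wild-type groups was not analysed here. Total counts ran from 20597475 to 26884477 per library, and 23301 to 24108 genes had at least 1 count. Of 32520 genes, 20098 had enough counts to be tested, and these held 99.9% of all counts. A gene is called below when its edgeR quasi-likelihood p, adjusted over the 20098 genes, lies under 0.05. Fold changes are on the log2 scale, given ± SE. Genes named for the largest changes had no overlap in CPM (counts scaled to library size) between the groups compared. Such separation was seen in 27.6% of all tested genes for TCDD in wild type, 37.3% for TCDD in mutants, 23.6% for the mutation in DMSO and 37.1% for the mutation in TCDD. Chance alone gives 10% for 3 against 3 libraries, 2.86% for 4 against 4 and 5.71% for 3 against 4.

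The targeted gene wfikkn1 (ENSDARG00000101364) was low in vehicle and was induced by TCDD in both lines. Wild-type DMSO libraries held 10, 12 and 19 wfikkn1 counts and wild-type TCDD libraries 214, 454 and 520. Mutant DMSO libraries held 0, 0, 4 and 3 counts, and mutant TCDD libraries 14, 15, 21 and 22. In CPM the means were 0.61 ± 0.214 (SD, n = 3), 17.2 ± 7.21 (SD, n = 3), 0.076 ± 0.0908 (SD, n = 4) and 0.758 ± 0.192 (SD, n = 4) in the same order. With TCDD, wfikkn1 rose by 4.80 ± 0.41 in wild type (edgeR adjusted p = 2.56e-06) and by 3.25 ± 0.62 in mutants (edgeR adjusted p = 7.74e-04). It was lower in mutants than in wild type in DMSO (-2.95 ± 0.68, edgeR adjusted p = 0.00737) and with TCDD (-4.50 ± 0.36, edgeR adjusted p = 4.16e-07). The difference between the TCDD effects was -1.55 ± 1.01 and was not called (edgeR adjusted p = 0.369). Each mutant library thus lay below every wild-type library of the same exposure, in the direction of its label, although the mutant DMSO level rests on a handful of reads. A floor of 3 counts corresponds to 0.112 to 0.146 CPM in these libraries.

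**Figure D1:**
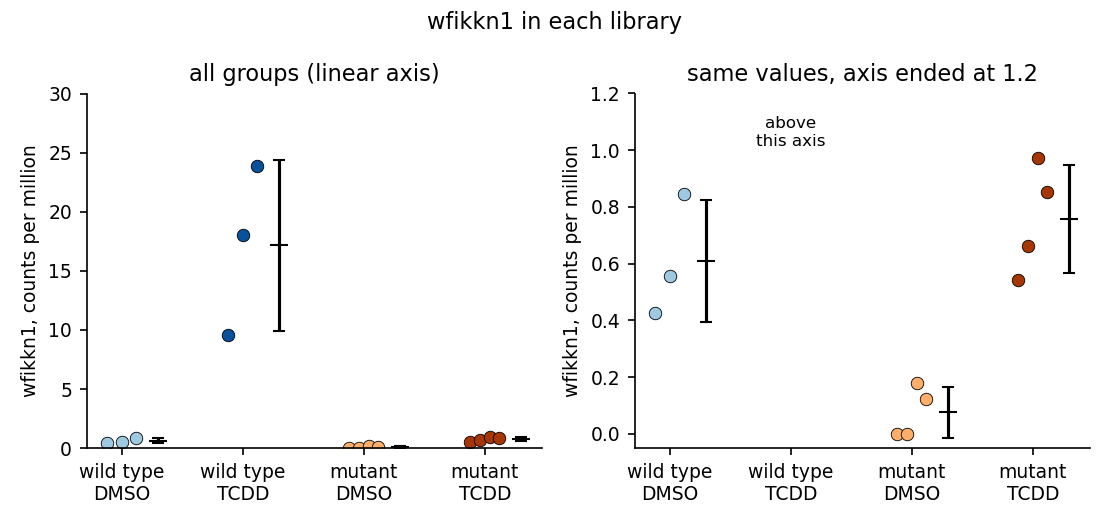
wfikkn1 in CPM (vertical axes) for each library (points) of the 4 groups, with the mean and SD beside them. The left panel shows wild-type TCDD libraries from 9.56 to 23.9 CPM, and the right panel shows the remaining groups on an axis that ends at 1.2 CPM.

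The libraries separated by line and by exposure. On the 500 most variable genes, the first principal component held 57.5% of the variance and placed every wild-type library on the opposite side of 0 from every mutant library. The second held 23.5% and moved in opposite directions with TCDD in the 2 lines. On it, wild-type libraries lay at 11.22 to 31.25 in DMSO and -17.11 to -6.005 with TCDD. Mutant libraries lay at -31.59 to 0.4166 in DMSO and 5.325 to 13.83 with TCDD. The third, with 7.60%, placed every DMSO library on the opposite side from every TCDD library. Libraries of the same group also differed along a shared axis. The first axis of variation within groups, computed over 15374 genes with a mean log2 CPM of at least 1, held 29.1% of the within-group variance, against 13.6% for the second. Scores of the libraries on this axis were -0.962, 10.3 and -41.3 in wild-type DMSO, 31, 16.6 and 20.9 in wild-type TCDD, 26.9, 13.4, -10.4 and 32.2 in mutant DMSO, and -28.6, -30.6, -12.3 and -27.1 in mutant TCDD. The scores therefore moved with the groups, up with TCDD in wild type and down with TCDD in mutants. Since the scores keep differences between groups, a fit with the score as a term also removes part of any real group difference along the axis. Calls that end with that term, in any comparison below, thus do not tell an axis shared with the libraries from a real effect. The 769 genes with the highest weights on this axis had median log2 fold changes of 1.05 with TCDD in wild type, -1.17 with TCDD in mutants, 0.755 for the mutation in DMSO, -1.52 for the mutation in TCDD and -2.17 for the difference of the TCDD effects. Of the gene lists, ribosomal proteins (median at percentile 13.8 of the weights), epidermis (19.4) and photoreceptor (7.33) had low weights, and erythroid (73.6) and TGF-beta genes (67.3) had high ones.

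**Figure D2:**
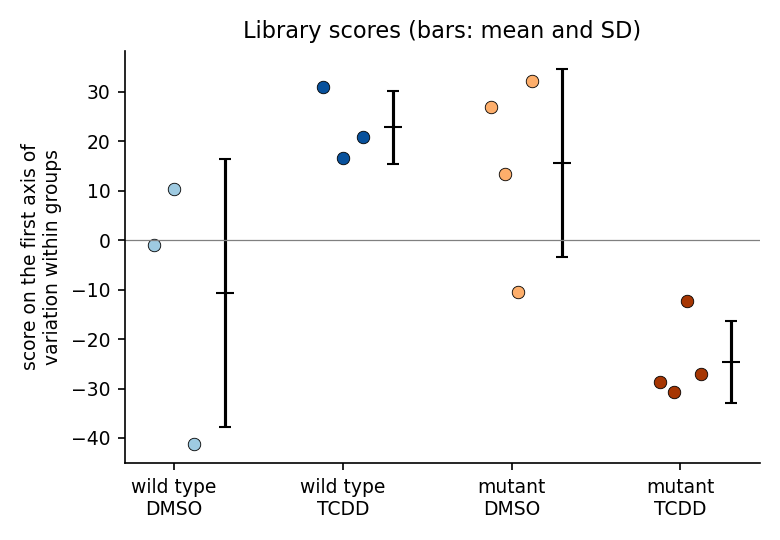
Score of each library (points) on the first axis of variation within groups (vertical axis, no unit) for the 4 groups, with mean and SD beside the points. Wild-type TCDD libraries lie between 16.6 and 31, mutant TCDD libraries between -30.6 and -12.3, and the DMSO groups spread from -41.3 to 32.2.

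The first comparison asks how wild-type embryos responded to TCDD. Cytochrome P450 genes of xenobiotic metabolism rose the most, with cyp1a at 19.6 ± 2.2 CPM in DMSO and 3137 ± 47 CPM with TCDD (SD, n = 3 each), a log2 change of 7.32 ± 0.13 (edgeR adjusted p = 3.38e-16). They were followed by cyp1c2 (5.64 ± 0.15), the AHR repressor gene ahrra (5.30 ± 0.23), cyp1c1 (5.29 ± 0.14), wfikkn1 itself and fgf7, a fibroblast growth factor (3.91 ± 0.27), all with edgeR adjusted p at or under 2.56e-06. Other genes among the largest rises were the mechanosensitive channel gene PIEZO2 (1 of many) (4.71 ± 0.96), ext1b, an enzyme gene of heparan sulfate synthesis (3.6 ± 0.65), and CSRNP3 (3.52 ± 0.68), with edgeR adjusted p between 0.00304 and 0.00575. These last 3 genes fell with TCDD in the mutants. The largest falls were smaller: the zinc finger gene znf1094 (-2.72 ± 0.64), the hemopexin gene hpxa (-1.81 ± 0.48), pdha1a of pyruvate dehydrogenase (-1.75 ± 0.28), the splicing factor gene prpf38a (-1.66 ± 0.41), dre-mir-125a-2 (-1.53 ± 0.37). After these came prolactin prl (-1.44 ± 0.29), otos (-1.33 ± 0.26), mfsd2ab, a lysophospholipid transporter gene (-1.25 ± 0.28), endothelin edn2 (-1.21 ± 0.19) and the ionocyte cotransporter gene slc12a10.2 (-1.20 ± 0.21), with edgeR adjusted p from 0.00141 to 0.0195. At most 3 counts were held by 2 of 3 DMSO libraries for PIEZO2 (1 of many) and by 2 of 3 TCDD libraries for znf1094, so that neither fold is a bound. Reads of znf1094 can also be shared with family members.

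Of 12 measured AHR battery genes, 9 rose in wild type, none fell and 3 were not called, with 10 higher when adjusted over the list alone. The list's camera adjusted p was 1.06e-18, and adjusted p = 1.16e-04 with an estimated correlation. Besides those named above, its called members were ahrrb (5.55 ± 0.89), the forkhead gene foxq1a (3.20 ± 0.17), nfe2l2b (1.77 ± 0.15), the TCDD-inducible polymerase gene tiparp (1.19 ± 0.11) and foxq1b (0.88 ± 0.20). Wild-type DMSO libraries had 0, 0 and 0.0445 CPM of ahrrb, under the floor of 3 counts, so that its fitted fold is not a bound. The members that were not called had log2 changes of 0.12 ± 0.14 for cyp1d1, 0.25 ± 0.17 for nqo1 and 0.44 ± 0.14 for the glucuronosyltransferase gene ugt1ab, with edgeR adjusted p of 0.597, 0.353 and 0.0507. Among 8 AHR receptors and partners, ahr2, the main TCDD receptor of zebrafish, rose by 1.00 ± 0.09 (edgeR adjusted p = 3.47e-06) and 7 were not called (camera adjusted p = 0.248, 3 higher when adjusted over the list alone). Oxidative stress genes were mostly not called: 2 of 19 rose, gstp1 (1.1 ± 0.12) and the heme oxygenase gene hmox1a (1.5 ± 0.21), 1 fell and 16 were not called (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.651).

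Other lists passed the preset test in wild type and lost the call with an estimated correlation. Of 85 ribosomal protein genes, 40 rose, none fell and 45 were not called (54 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.17e-11, adjusted p = 0.677 with an estimated correlation). Examples are rps4x (0.64 ± 0.10) and rpl13 (0.67 ± 0.12). Of 13 mitochondrially encoded genes, 6 rose and 7 were not called (7 higher adjusted over the list alone, camera adjusted p = 0.0318, adjusted p = 0.677 with an estimated correlation). Here mt-nd6 stood at 0.74 ± 0.12 and mt-nd2 at 0.52 ± 0.10. Of 34 liver and yolk syncytium genes, 9 rose and 25 were not called (10 higher adjusted over the list alone, camera adjusted p = 0.0266, adjusted p = 0.677 with an estimated correlation). Called members include coagulation factor f5 (0.73 ± 0.14) and the apolipoprotein genes apoc1 (0.64 ± 0.14) and apoeb (0.42 ± 0.09). Of 31 fast muscle genes, 8 rose and 23 were not called (10 higher adjusted over the list alone, camera adjusted p = 0.0177, adjusted p = 0.677 with an estimated correlation). Among these are the myosin light chain gene myl1 (0.45 ± 0.09) and the calcium release channel gene ryr3 (0.74 ± 0.16). Cartilage genes went the other way, with 8 of 22 lower, 1 higher and 13 not called (10 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0318, adjusted p = 0.617 with an estimated correlation). Examples are epyc (-0.50 ± 0.08), col9a3 (-0.50 ± 0.09), sox9b (-0.63 ± 0.14) and sox6 (-0.36 ± 0.08). Of 26 sterol synthesis genes, 5 fell, 1 rose and 20 were not called (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0075, adjusted p = 0.43 with an estimated correlation). Here idi1 stood at -0.67 ± 0.11 and fdft1 at -0.78 ± 0.18. Of 10 bone genes, 2 fell, col10a1a among them (-0.63 ± 0.12), and 8 were not called (4 lower adjusted over the list alone, camera adjusted p = 0.403). Of 30 matrix and fin fold genes, 7 rose, 2 fell and 21 were not called (9 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.403). Here the actinodin gene and3 stood at 0.72 ± 0.12.

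In all, 1777 genes were higher and 1156 lower with TCDD in wild type, of which 730 and 66 changed at least 2-fold. Library scores on the within-group axis rose with TCDD here, and ribosomal, cartilage, liver and fast muscle genes lay at median percentiles 13.8, 27, 27.1 and 30.4 of the weights. When scores rise, low weights go with a fall relative to other genes. Cartilage genes moved that way, while the ribosomal, liver and fast muscle lists moved against it. DESeq2 with its own size factors called 1776 and 1798, a fit to the 6 wild-type libraries alone called 773 and 397, leaving out wild-type DMSO replicate 1 left 1177 higher, and leaving out wild-type TCDD replicate 3 left 602 lower. In the fit to the wild-type libraries alone, foxq1b, apoeb and myl1 were not called (edgeR adjusted p = 0.0504, 0.0667 and 0.073). Without wild-type TCDD replicate 3, hpxa, prpf38a and dre-mir-125a-2 were not called (edgeR adjusted p = 0.0905, 0.0626 and 0.0529), nor was hpxa without wild-type DMSO replicate 1 (0.0612). Leaving out 1 library also ended the camera call of the cartilage (replicate 1 or 4 of DMSO or 1 of TCDD, adjusted p = 0.0649 to 0.094), fast muscle (1 or 3 of DMSO, 0.0744 to 0.179), liver and yolk (1 of either, 0.0652 to 0.205) and mitochondrial (3 or 4 of DMSO, 1 or 3 of TCDD, 0.0662 to 0.247) lists. With the library score as a term, added after seeing the data, 602 and 396 genes were called. Calls ended for PIEZO2 (1 of many) (2.2), f5 (0.42), ryr3 (0.36), sox6 (-0.28) and col10a1a (-0.42), which shrank (edgeR adjusted p = 0.0526 to 0.126). They also ended for hpxa (-1.83), dre-mir-125a-2 (-1.54) and mfsd2ab (-1.14), which kept most or all of their change (edgeR adjusted p = 0.0542 to 0.079). The term also ended the camera calls of the cartilage (adjusted p = 0.283) and mitochondrial (0.0605) lists.

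**Figure D3:**
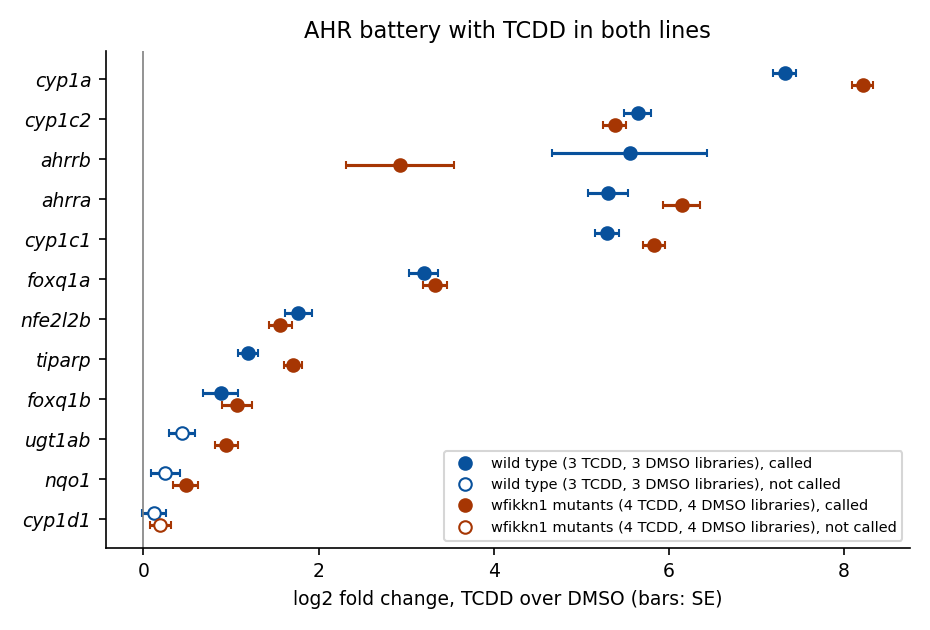
Log2 fold change of TCDD over DMSO (horizontal axis, bars are SE) for the 12 measured AHR battery genes in wild type and in wfikkn1 mutants, with open points for genes not called. cyp1a stands at 7.32 in wild type and 8.21 in mutants, and cyp1d1 was not called in either line.

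The second comparison asks how wfikkn1 mutants responded to TCDD. The same P450 genes led: cyp1a went from 16.7 ± 2.38 to 4968 ± 288 CPM (SD, n = 4 each), a log2 change of 8.21 ± 0.12 (edgeR adjusted p = 8.23e-18). Here ahrra stood at 6.14 ± 0.21, cyp1c1 at 5.83 ± 0.13 and cyp1c2 at 5.38 ± 0.13. The remaining largest rises were fgf7 (3.86 ± 0.23), foxq1a (3.33 ± 0.14), wfikkn1, the conjugating enzyme genes ugt1b1 (3.09 ± 0.11) and sult6b1 (3.07 ± 0.16) and the cathepsin L gene ctsl.1 (3.04 ± 0.29), with edgeR adjusted p at or under 3.07e-06 apart from wfikkn1. The largest falls were PIEZO2 (1 of many) (-4.14 ± 0.88), the hemicentin gene hmcn2 (-4.00 ± 0.64), the transcription factor gene tfe3a (-3.81 ± 0.65), mri1 of methionine salvage (-3.57 ± 0.49), the TGF-beta receptor gene tgfbr1b (-3.40 ± 0.56). They were followed by the mannosidase gene man2a1 (-3.40 ± 0.58), the ubiquitin ligase gene itchb (-3.34 ± 0.51), palm2 (-3.29 ± 0.63), CSRNP3 (-3.23 ± 0.66) and the metalloproteinase gene mmp24 (-3.22 ± 0.50), with edgeR adjusted p from 6.41e-05 to 0.00172. Scores on the within-group axis were lower with TCDD in the mutants, and the 769 genes of highest weight had a median change of -1.17. The library score, as a term added after seeing the data, also takes up part of any real TCDD effect along the axis. With it, 7 of these 10 falls were not called. Of these, PIEZO2 (1 of many) (0.17) and CSRNP3 (0.07) turned, and hmcn2 (-1.77), man2a1 (-1.15), tgfbr1b (-0.82), tfe3a (-0.80) and palm2 (-0.34) shrank (edgeR adjusted p = 0.0753 to 0.953). In 2 of 4 mutant TCDD libraries PIEZO2 (1 of many) lay under the floor, so that its fold is not a bound.

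Of the 12 AHR battery genes, 11 rose in mutants and cyp1d1 was not called (0.19 ± 0.12, edgeR adjusted p = 0.213). The same 11 were higher when adjusted over the list alone (camera adjusted p = 5.3e-15, adjusted p = 3.42e-04 with an estimated correlation). They included ahrrb (2.93 ± 0.62), tiparp (1.71 ± 0.10), nfe2l2b (1.56 ± 0.13), foxq1b (1.07 ± 0.17), ugt1ab (0.95 ± 0.13) and nqo1 (0.48 ± 0.14), the last of which was not called without mutant TCDD replicate 2 or 4 (edgeR adjusted p = 0.0581 and 0.0554). The DMSO level of ahrrb was under the floor in 3 of 4 mutant libraries too. Of the 8 receptors and partners, 4 rose, 2 fell and 2 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.506). Among them ahr2 rose by 0.62 ± 0.08 and arnt2, a dimerization partner, fell by 0.53 ± 0.08. Of 19 oxidative stress genes, 7 rose and 12 were not called (7 higher adjusted over the list alone, camera adjusted p = 0.0475, adjusted p = 0.552 with an estimated correlation). Here gstp1 and hmox1a both stood at 1.63 (SE 0.11 and 0.19) and gclc of glutathione synthesis at 0.36 ± 0.08.

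Ribosomal protein genes rose in mutants as well, with 64 of 85 higher, 1 lower and 20 not called (69 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.36e-16, adjusted p = 0.552 with an estimated correlation), rps4x at 0.78 ± 0.09 and rps15a at 0.98 ± 0.12. Liver and yolk syncytium genes had 19 of 34 higher, 1 lower and 14 not called (19 higher and 2 lower adjusted over the list alone, camera adjusted p = 8.62e-05, adjusted p = 0.552 with an estimated correlation). Here apoc1 stood at 1.27 ± 0.12 and apoeb at 0.91 ± 0.08. Lens genes, mostly crystallins of a family with near-identical members, had 15 of 30 higher, 1 lower and 14 not called (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.41e-04, adjusted p = 0.552 with an estimated correlation). Examples are crygn2 (0.87 ± 0.13) and cryba1l1 (0.70 ± 0.10). Fast muscle genes had 18 of 31 higher, 3 lower and 10 not called (19 and 4 adjusted over the list alone, camera adjusted p = 0.00672, adjusted p = 0.601 with an estimated correlation). Among these are the actin gene acta1b (0.69 ± 0.09) and the tropomyosin gene tpma (0.92 ± 0.12). Of 13 mitochondrially encoded genes, 7 rose and 6 were not called (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.031, adjusted p = 0.783 with an estimated correlation), mt-nd6 at 0.92 ± 0.11 and mt-atp6 at 0.68 ± 0.06. Of 22 cartilage genes, 10 fell, 5 rose and 7 were not called (11 lower and 5 higher adjusted over the list alone, camera adjusted p = 0.13), with the aggrecan genes acana (-0.90 ± 0.10) and acanb (-1.82 ± 0.21) and hapln1a (-0.52 ± 0.06) among the lower. Of 10 bone genes, 4 fell, including col10a1a (-0.75 ± 0.10) and the osteoblast factor gene sp7 (-0.99 ± 0.14), 1 rose and 5 were not called (4 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.64).

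Heat shock and unfolded protein genes had 14 of 31 higher, 5 lower and 12 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.0592), hspb6 at 1.26 ± 0.17 and hsp90aa1.2 at 0.79 ± 0.11. Vascular genes went both ways, 7 of 20 higher, 6 lower and 7 not called (7 and 6 adjusted over the list alone, camera adjusted p = 0.955). Here the scavenger receptor gene stab1 stood at -1.12 ± 0.13 and the VEGF receptor gene kdr at -0.60 ± 0.10. Leukocyte and inflammation genes had 5 of 19 higher, 5 lower and 9 not called (5 and 5 adjusted over the list alone, camera adjusted p = 0.744). Here cebpb stood at 0.91 ± 0.16 and mmp9 at 1.14 ± 0.20. Of 26 retinoid and steroid metabolism genes, 5 rose, 5 fell and 16 were not called (5 and 5 adjusted over the list alone, camera adjusted p = 0.957). Here pck1 of gluconeogenesis stood at 2 ± 0.15 and the thyroid hormone receptor gene thrb at -0.76 ± 0.07. Altogether 3524 genes were higher and 3729 lower with TCDD in mutants, of which 354 and 904 changed at least 2-fold. With the library score as a term, the counts were 947 and 1248. Calls ended for gclc (0.22), nqo1 (0.19) and kdr (-0.34), which shrank (edgeR adjusted p = 0.0617 to 0.574), and for ahrrb, which kept most of its change (2.54, edgeR adjusted p = 0.123). So did the camera calls of the oxidative stress (adjusted p = 0.0827) and fast muscle (0.0844) lists. The camera call of the oxidative stress list ended without mutant DMSO replicate 2 or 3 or mutant TCDD replicate 1 (adjusted p = 0.0635 to 0.0814), and that of the mitochondrial list without mutant DMSO replicate 4 or mutant TCDD replicate 1 or 4 (0.0595 to 0.0852). When axis scores fall, low weights go with a rise relative to other genes. The ribosomal, lens, heat shock, liver and fast muscle lists, at median percentiles 13.8, 22.8, 26, 27.1 and 30.4, moved that way. Cartilage genes (27) moved against it, and the oxidative stress (51.4) and mitochondrial (55.7) lists had middle weights.

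The next comparison asks whether the 2 lines differed in their response to TCDD, tested as the difference of the TCDD effects, mutants minus wild type. The AHR battery was induced in both lines, and 3 of its 12 genes differed. Of these, cyp1a rose more in mutants (0.89 ± 0.14, edgeR adjusted p = 3.72e-04), as did cyp1c1 (0.54 ± 0.16, edgeR adjusted p = 0.0396) and tiparp (0.51 ± 0.15, edgeR adjusted p = 0.0316). For cyp1c1 the larger rise started from a lower DMSO level, 9.68 to 13.4 CPM in mutants against 17.7 to 20.1 in wild type. With TCDD, cyp1c1 was not higher in mutants, at 573 to 753 CPM against 700 to 838 in wild type. The other 9 were not called, with differences of 0.84 ± 0.36 for ahrra, 0.51 ± 0.19 for ugt1ab, 0.23 ± 0.22 for nqo1, 0.19 ± 0.26 for foxq1b, 0.13 ± 0.21 for foxq1a, 0.07 ± 0.18 for cyp1d1, -0.21 ± 0.20 for nfe2l2b, -0.26 ± 0.19 for cyp1c2 and -2.62 ± 1.32 for ahrrb, whose DMSO level was under the floor in 6 of 7 libraries. The list had 3 higher adjusted over the list alone (camera adjusted p = 0.206). Many genes shared the smallest adjusted p (1.99e-04 in edgeR). Of these, the 10 named genes with the lowest unadjusted p rose with TCDD in wild type and fell in mutants: nfixb, a nuclear factor I gene (-2.37 ± 0.25), nyap2b (-1.49 ± 0.17), the integrin gene itga9 (-2.26 ± 0.25), the netrin receptor gene dcc (-2.43 ± 0.27), crim1 (-3.25 ± 0.37). To these belong also kank2 (-5.37 ± 0.63), ism2a (-4.29 ± 0.51), sh3pxd2aa (-3.63 ± 0.43), tbc1d9 (-4.70 ± 0.56) and the receptor phosphatase gene ptprdb (-2.19 ± 0.26).

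No list passed the camera test of the difference, whose lowest adjusted p was 0.0522. Of 31 TGF-beta, activin and myostatin genes, 8 were lower, none higher and 23 not called (9 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.366). These include the receptor genes tgfbr1b (-5 ± 0.81), tgfbr1a (-2.62 ± 0.47) and acvr1bb (-1.80 ± 0.28). The medians of this list (0.055), of the circadian list (0.0267) and of the cardiac list (0.0832) were above 0 while their tests pointed down. Of 30 matrix genes, 7 were lower and 23 not called (7 lower adjusted over the list alone, camera adjusted p = 0.336). Here the fibrillin gene fbn2b stood at -1.80 ± 0.28. Of 24 neuron genes, 2 were lower and 22 not called (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.363). Here the glutamate transporter gene slc17a6a stood at -1.95 ± 0.25. Of 29 circadian genes, 3 were lower, clocka at -3.08 ± 0.53 among them, and 26 not called (3 lower adjusted over the list alone, camera adjusted p = 0.937). Of 22 myogenic regulators, 2 were lower and 20 not called (3 lower adjusted over the list alone, camera adjusted p = 0.332). Of 18 cardiac genes, 2 were lower, including the calcium channel gene cacna1c (-4.29 ± 0.58), and 16 not called (4 lower adjusted over the list alone, camera adjusted p = 0.748). None of 15 photoreceptor genes was called, here or adjusted over the list alone (camera adjusted p = 0.516). Of single members, egln2, a hypoxia-inducible factor hydroxylase gene (-2.92 ± 0.40), stab1 (-1.35 ± 0.20), kita (-1.76 ± 0.28), acanb (-2.43 ± 0.31) and ryr1b (-1.15 ± 0.19) were lower, and pck1 (1.08 ± 0.22) and apoea (0.92 ± 0.18) were higher.

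In all, 372 genes had a higher and 2044 a lower TCDD effect in mutants than in wild type, of which 46 and 1380 differed at least 2-fold. The higher count was 832 in DESeq2, 609 without wild-type DMSO replicate 1, 160 without wild-type DMSO replicate 4, 132 without wild-type TCDD replicate 1, 222 and 224 without mutant DMSO replicate 2 or 4, and 155, 234 and 237 without mutant TCDD replicate 2, 3 or 4. Of the genes called in both lines, 537 rose in both (311.6 would overlap by chance from independent lists), 726 fell in both (214.5 by chance), 759 rose in wild type and fell in mutants (329.7 by chance), and 6 fell in wild type and rose in mutants (202.7 by chance). Across all 20098 genes, which are not independent replicates, the TCDD effects had a Pearson r of -0.108 and a Spearman rho of 0.165. Of the 759 opposite genes, 659 had an axis weight, and 445 of these (67.5%) lay among the highest 5% of weights, against 2 of 1224 genes that changed in the same direction. With the library score as a term, added after seeing the data, edgeR called no gene for the difference in either direction, with 1407 genes at an unadjusted p under 0.05. With it, the differences of cyp1a, cyp1c1 and tiparp were 0.64, 0.34 and 0.81 (edgeR adjusted p = 0.559, 0.844 and 0.395). In the fit without that term, cyp1a stayed called with any 1 library left out, while cyp1c1 was not called without wild-type DMSO replicate 3 or 4, wild-type TCDD replicate 3 or 4, mutant DMSO replicate 1 or 4 or mutant TCDD replicate 1 or 4 (edgeR adjusted p = 0.0505 to 0.0855). The gene tiparp was not called without wild-type DMSO replicate 3, wild-type TCDD replicate 3 or 4, mutant DMSO replicate 3 or 4 or mutant TCDD replicate 3 or 4 (edgeR adjusted p = 0.053 to 0.0896).

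**Figure D4:**
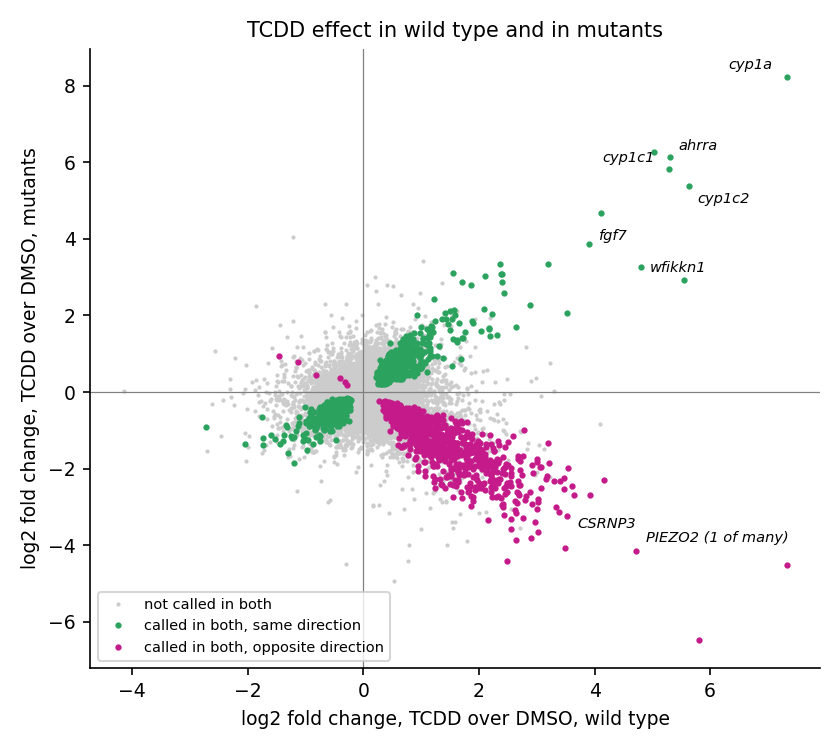
Log2 fold change of TCDD over DMSO in wild type (horizontal axis) and in mutants (vertical axis) for the 20098 tested genes (points), coloured by whether a gene was called in both lines and in which directions. The AHR genes lie at the upper right, and 759 genes lie at the lower right, higher with TCDD in wild type and lower in mutants.

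Mutant and wild-type embryos were compared within each exposure, first in DMSO. Genes called for the mutation differ between 2 lines, and the mutation cannot be told apart here from other differences between those lines. Mutant embryos had higher counts of phf5a, a splicing factor gene (4.74 ± 0.39), the caspase gene casp6 (4.30 ± 0.34), arhgef28b (3.91 ± 0.31), rrm2 ENSDARG00000020711 (3.66 ± 0.37), dicp1.16 (3.51 ± 0.30). The next were tnrc6c2 (3.44 ± 0.35), the cadherin gene cdh29 (2.91 ± 0.34), CCDC134 (2.67 ± 0.22), the thyrotropin-releasing hormone receptor gene trhra (2.5 ± 0.49) and znf1094 (2.32 ± 0.41), with edgeR adjusted p from 4.6e-07 to 0.00227. The largest falls were the class I histocompatibility gene mhc1uba (-8.63 ± 0.72), the actin gene actc1a ENSDARG00000076126 (-6.83 ± 0.24), ldb2b (-6.19 ± 0.25), bsdc1 (-6.06 ± 0.37). Next were rrm2 ENSDARG00000078069 (-5.68 ± 0.15), tapt1b (-5.67 ± 0.28), the RNA-binding protein gene tia1 (-5.65 ± 0.39), the ADP/ATP carrier gene slc25a4 (-4.28 ± 0.28), fabp7b (-4.23 ± 0.48) and mpdu1a (-3.75 ± 0.32), with edgeR adjusted p at or under 1.68e-05. The values of mhc1uba, actc1a, rrm2, dicp1.16 and znf1094 are uncertain, since each has near-identical copies or family members with which reads can be shared or exchanged. The rrm2 IDs, for the small subunit of ribonucleotide reductase, changed in opposite directions, and the sum of both was 165.3 ± 14.1 CPM in wild type (SD, n = 3) and 187.9 ± 12.3 CPM in mutants (SD, n = 4). The fall of mhc1uba is against mutant libraries with 0.0451 CPM at most, under the floor of 3 counts, so that its fitted fold is not a bound. Nor are those of tia1 and bsdc1, with at most 3 counts in 3 of 4 mutant libraries, and of fabp7b, in 2 of 4.

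Erythroid genes had 13 of 26 lower, none higher and 13 not called (16 lower adjusted over the list alone, camera adjusted p = 1.52e-05, adjusted p = 0.315 with an estimated correlation). Here the globin gene hbae3 stood at -1.46 ± 0.15 and the carbonic anhydrase gene cahz at -0.67 ± 0.08. Hypoxia and glycolysis genes had 20 of 39 lower, 2 higher and 17 not called (24 and 2 adjusted over the list alone, camera adjusted p = 1.52e-05, adjusted p = 0.315 with an estimated correlation). Here ankrd37 stood at -2.31 ± 0.31, the phosphofructokinase gene pfkma at -0.70 ± 0.10 and myoglobin mb at -1.36 ± 0.21. Lens genes had 9 of 30 lower and 21 not called (9 lower adjusted over the list alone, camera adjusted p = 2.56e-04, adjusted p = 0.315 with an estimated correlation). Here bfsp2 stood at -0.57 ± 0.08 and cryba4 at -1.47 ± 0.26. Pigment cell genes had 9 of 19 lower and 10 not called (10 lower adjusted over the list alone, camera adjusted p = 0.00377, adjusted p = 0.155 with an estimated correlation), with the melanin synthesis genes oca2 (-0.96 ± 0.16), tyrp1a (-0.73 ± 0.14) and dct (-0.55 ± 0.11). Fast muscle genes had 13 of 31 lower, 1 higher and 17 not called (18 and 3 adjusted over the list alone, camera adjusted p = 0.00212, adjusted p = 0.422 with an estimated correlation). Here the creatine kinase gene ckma stood at -0.98 ± 0.22 and, as the higher one, the myosin light chain gene mylpfa at 2.98 ± 0.67. The latter is no bound, since wild-type libraries had 0.171, 0.0927 and 0.0445 CPM of it, under the floor in 2 of 3. In the same libraries the light chain gene myl1 had 356 to 454 CPM, and whether this gene ID holds all reads of mylpfa was not tested. Slow muscle genes had 5 of 14 lower and 9 not called (6 lower adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.315 with an estimated correlation). Here smyhc1 stood at -0.84 ± 0.18.

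Liver and yolk syncytium genes had 10 of 34 lower, 1 higher and 23 not called (14 and 1 adjusted over the list alone, camera adjusted p = 0.00118, adjusted p = 0.343 with an estimated correlation). Here serpina1 stood at -1.09 ± 0.19 and apoea at -0.74 ± 0.13. Ribosomal protein genes had 10 of 85 lower, 1 higher and 74 not called (8 and 1 adjusted over the list alone, camera adjusted p = 0.00146, adjusted p = 0.748 with an estimated correlation). Here rpl7a stood at -0.48 ± 0.10. Heat shock genes had 6 of 31 lower, 1 higher and 24 not called (7 and 2 adjusted over the list alone, camera adjusted p = 0.0169, adjusted p = 0.315 with an estimated correlation). Here hsp70l stood at -2.02 ± 0.37. Epidermis genes had 5 of 26 lower and 21 not called (5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.687), the keratin gene krt4 at -2.18 ± 0.28 among them. Hatching gland genes had 3 of 10 lower, 1 higher and 6 not called (5 and 1 adjusted over the list alone, camera adjusted p = 0.157). Here the astacin protease gene npsn stood at -1.82 ± 0.18 and p4hb at -1.15 ± 0.20. Of the myogenic regulators, 2 of 22 were higher, 2 lower and 18 not called (2 and 2 adjusted over the list alone, camera adjusted p = 0.817). Here mef2ca stood at -0.98 ± 0.09 and pax3a at 0.75 ± 0.12. None of 21 glia and neural progenitor genes was called, here or adjusted over the list alone (camera adjusted p = 0.687). Of the AHR battery, cyp1c1 was lower (-0.70 ± 0.12), foxq1a (0.70 ± 0.16) and nfe2l2b (0.65 ± 0.15) were higher and 9 were not called (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.687). The genes not called were cyp1a (-0.23 ± 0.10), cyp1c2 (0.40 ± 0.15), cyp1d1 (0.33 ± 0.13), ahrra (-0.63 ± 0.33), ahrrb (1.99 ± 1.22), tiparp (-0.09 ± 0.11), nqo1 (0.30 ± 0.16), foxq1b (0.25 ± 0.19) and ugt1ab (-0.31 ± 0.14).

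In DMSO, 1650 genes were higher and 1728 lower in mutants, with 610 and 584 changed at least 2-fold. A fit to the DMSO libraries alone called 1003 and 1169, without foxq1a (edgeR adjusted p = 0.0542), leaving out wild-type DMSO replicate 4 left 928 and 1136, and leaving out mutant DMSO replicate 1 or 4 left 1039 or 1053 higher. With the library score as a term, added after seeing the data, 819 and 1015 were called. The fall of wfikkn1 then stood at -2.41 and was not called, nor were ckma (-0.66) and rpl7a (-0.30, edgeR adjusted p = 0.0606, 0.0825 and 0.0707). The camera calls of the heat shock (adjusted p = 0.152) and ribosomal (0.364) lists ended too. Without wild-type DMSO replicate 4, which had the lowest axis score, the camera calls of the ribosomal, heat shock and slow muscle lists ended (adjusted p = 0.525, 0.117 and 0.0759), and that of slow muscle also ended without mutant DMSO replicate 3 (0.0665). Across genes, axis weights went with the changes in DMSO at a Pearson r of 0.403, so that low weights went with a fall. The ribosomal, lens, slow muscle, heat shock, liver, hypoxia, fast muscle and pigment cell lists, at median percentiles 13.8 to 36.1, moved that way. Erythroid genes (73.6) moved against it.

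With TCDD, most of the same genes stood apart between the lines. Of those higher in mutants in DMSO, trhra was lower with TCDD, at 0.596 ± 0.239 CPM (SD, n = 4) against 3.47 ± 0.192 in wild type (SD, n = 3). Those higher in mutants were casp6 (5.19 ± 0.40), znf1094 (4.12 ± 0.56), phf5a (3.84 ± 0.35), arhgef28b (2.87 ± 0.29), dicp1.16 (2.79 ± 0.29), rrm2 ENSDARG00000020711 (2.66 ± 0.35), CCDC134 (2.49 ± 0.22), tnrc6c2 (2.43 ± 0.34), the tetraspanin gene tspan4b (2.38 ± 0.30) and ndufs7 of respiratory complex I (2.32 ± 0.53), with edgeR adjusted p from 3.08e-07 to 0.00373. Those lower were mhc1uba (-9.35 ± 0.89), tia1 (-7.12 ± 0.44), bsdc1 (-6.04 ± 0.36), actc1a ENSDARG00000076126 (-5.78 ± 0.23), rrm2 ENSDARG00000078069 (-5.63 ± 0.15), ldb2b (-5.60 ± 0.24), fabp7b (-5.17 ± 0.50), PIEZO2 (1 of many) (-5.10 ± 0.89), tapt1b (-4.66 ± 0.26) and CSRNP3 (-4.65 ± 0.67), with edgeR adjusted p at or under 4.31e-04. In DMSO, PIEZO2 (1 of many) and CSRNP3 were higher in mutants instead. The copies named as uncertain in DMSO are uncertain here too, and the summed rrm2 IDs stood at 122.6 ± 14.7 CPM in wild type (SD, n = 3) and 186.1 ± 13.8 CPM in mutants (SD, n = 4). No mutant TCDD library had reads of mhc1uba, and tia1 lay between 0 and 0.139 CPM, at or under the floor in all 4, so that neither fold is a bound. The same holds for bsdc1 (3 of 4 libraries), fabp7b and PIEZO2 (1 of many) (2 of 4) and, in wild type, casp6 and znf1094 (2 of 3).

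Of 12 AHR battery genes, 6 were higher in TCDD-exposed mutants than in TCDD-exposed wild type and 6 were not called (7 higher adjusted over the list alone, camera adjusted p = 0.0311, adjusted p = 0.467 with an estimated correlation). The higher ones were foxq1a (0.83 ± 0.13), cyp1a (0.66 ± 0.09), nqo1 (0.53 ± 0.16), nfe2l2b (0.45 ± 0.14), tiparp (0.43 ± 0.10) and cyp1d1 (0.40 ± 0.13). The others were cyp1c1 (-0.16 ± 0.11), cyp1c2 (0.14 ± 0.11), ahrra (0.21 ± 0.15), ahrrb (-0.63 ± 0.47), foxq1b (0.43 ± 0.18) and ugt1ab (0.20 ± 0.14). Cell cycle genes had 13 of 31 higher, 1 lower and 17 not called (14 and 1 adjusted over the list alone, camera adjusted p = 3.54e-04, adjusted p = 0.567 with an estimated correlation). Here the replication gene mcm7 stood at 0.72 ± 0.14, the cyclin gene ccnb1 at 0.50 ± 0.10, bub1 at 0.50 ± 0.11 and, as the lower one, cenpf at -0.76 ± 0.15. Hypoxia and glycolysis genes had 17 of 39 lower, 1 higher and 21 not called (21 and 2 adjusted over the list alone, camera adjusted p = 3.54e-04, adjusted p = 0.556 with an estimated correlation). Here ankrd37 stood at -2.65 ± 0.30, egln2 at -2.37 ± 0.28 and egln3 at -1.32 ± 0.19. Erythroid genes, a list of high axis weights, had 11 of 26 lower, 1 higher and 14 not called (13 and 1 adjusted over the list alone, camera adjusted p = 0.0517). Here hbae3 stood at -0.97 ± 0.15 and slc25a37 at -3.32 ± 0.54. Pigment cell genes had 6 of 19 lower and 13 not called (6 lower adjusted over the list alone, camera adjusted p = 0.172). Here the tyrosinase gene tyr stood at -0.73 ± 0.09 and kita at -1.62 ± 0.20. Of 10 hatching gland genes, 2 were lower, npsn (-1.42 ± 0.18) and p4hb (-1.28 ± 0.20), 1 higher and 7 not called (2 and 1 adjusted over the list alone, camera adjusted p = 0.966). The myogenic list had 6 of 22 lower, mef2ca at -1.02 ± 0.09 among them, 1 higher and 15 not called (6 and 1 adjusted over the list alone, camera adjusted p = 0.259). Of 4 measured exocrine pancreas genes, 2 were higher, including the carboxypeptidase gene cpa4 (1.75 ± 0.38), and 2 not called (2 higher adjusted over the list alone, camera adjusted p = 0.299). Retinoid and steroid metabolism had 6 of 26 higher, rdh10a (0.78 ± 0.14) and crabp2b (0.80 ± 0.15) among them, 3 lower and 17 not called (7 and 3 adjusted over the list alone, camera adjusted p = 0.259).

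With TCDD, 2157 genes were higher and 3395 lower in mutants, with 378 and 1646 changed at least 2-fold, and 1430 were higher without wild-type TCDD replicate 1. With the library score as a term, added after seeing the data, 451 and 780 were called. Calls ended for PIEZO2 (1 of many) (-0.49), CSRNP3 (-1.19), slc25a37 (-1.40), cenpf (-0.27), ccnb1 (0.29), mcm7 (0.49), cpa4 (1.28), rdh10a (0.51), nqo1 (0.19) and cyp1d1 (0.32), which shrank (edgeR adjusted p = 0.119 to 0.838). They also ended for ndufs7 (2.41), crabp2b (0.78) and nfe2l2b (0.43), which kept their change (edgeR adjusted p = 0.0548 to 0.261). The term ended the camera call of the AHR list as well (adjusted p = 0.061). Without 1 library, the AHR list's camera call ended (wild-type TCDD replicate 4, adjusted p = 0.0951, or mutant TCDD replicate 1, 0.052). So did the edgeR calls of nqo1 (wild-type TCDD replicate 3 or 4, mutant TCDD replicate 2 or 4, adjusted p = 0.0529 to 0.0701), nfe2l2b (wild-type TCDD replicate 3, mutant TCDD replicate 1, 0.0777 to 0.0994) and cyp1d1 (wild-type TCDD replicate 4, mutant TCDD replicate 2 or 3, 0.0557 to 0.143).

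Between the exposures, 1901 genes were called for the mutation in both. Of these, 629 were higher in mutants under both (177.1 would overlap by chance from independent lists), 783 lower under both (291.9 by chance), 483 higher in DMSO and lower with TCDD (278.7 by chance) and 6 the reverse (185.5 by chance). The Pearson r of the effects over all tested genes was 0.40 and the Spearman rho 0.218. The gene wfikkn1 lies on chromosome 1 in the gene table of assembly GRCz12tu, which places 15057 of the tested genes. Genes called for the mutation were somewhat more frequent on that chromosome in DMSO (odds ratio 1.37, Fisher's exact test, adjusted p = 0.0197 over 25 chromosomes) and not detectably so with TCDD (odds ratio 1.04, Fisher's exact test, adjusted p = 0.864). For genes called under both exposures in the same direction the odds ratio was 1.81 (Fisher's exact test, adjusted p = 2.42e-04). The enrichment was not particular to chromosome 1: in DMSO chromosomes 12 and 20 had odds ratios of 1.37 and 1.38 (Fisher's exact test, adjusted p = 0.0329 and 0.0197). Chromosome 20 also had 1.33 with TCDD and 1.57 under both exposures (Fisher's exact test, adjusted p = 0.0208 and 0.0152). Calls for TCDD in wild type, a comparison within 1 line, had an odds ratio of 1.39 on chromosome 21 (Fisher's exact test, adjusted p = 0.0359). On chromosome 1 theirs was 0.787 (Fisher's exact test, adjusted p = 0.155). Odds ratios up to that size on a chromosome thus also arose without a difference between lines.

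**Figure D5:**
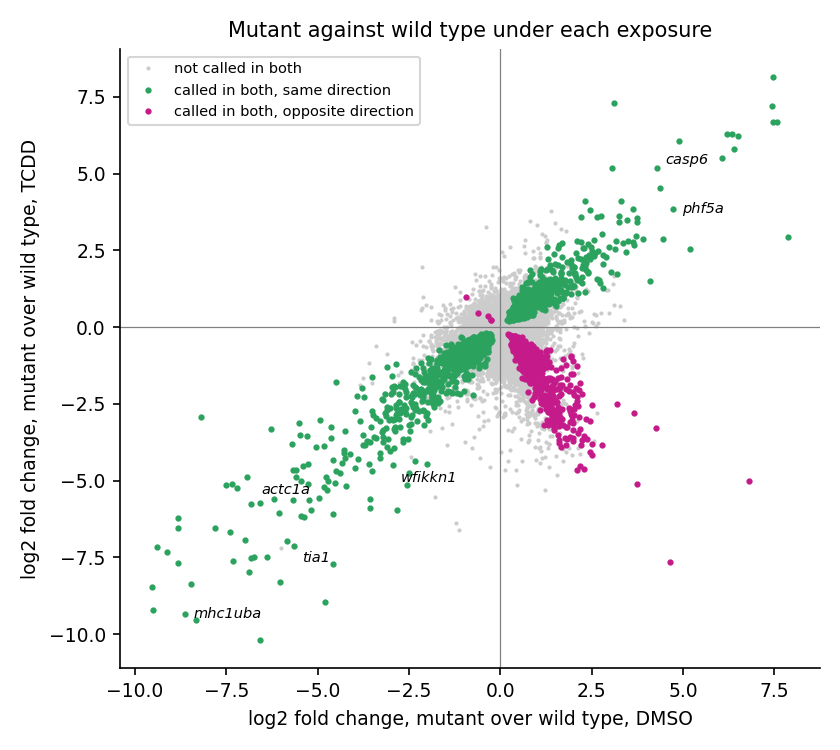
Log2 fold change of mutant over wild type in DMSO (horizontal axis) and with TCDD (vertical axis) for the 20098 tested genes (points), coloured by whether a gene was called under both exposures and in which directions. mhc1uba lies at -8.63 and -9.35, casp6 at 4.30 and 5.19, and 483 genes lie at the lower right, higher in DMSO and lower with TCDD.

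The authors' deposited tables of the same 4 pairwise comparisons hold only genes with a false discovery rate of at most 0.05. The authors' deposited tables list 2871 genes for TCDD in wild type (1702 higher, 1169 lower), 7244 for TCDD in mutants (3458 higher, 3786 lower), 3220 for the mutation in DMSO (1546 higher, 1674 lower) and 5455 for the mutation in TCDD (2107 higher, 3348 lower). Of the genes in the authors' deposited tables, 98% to 98.9% were called here with the same sign, and no log2 fold change differed by more than 0.00924.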

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

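The tests of the axis across genes, of exchanged exposure labels and of the library score as a term were chosen only after the result was seen.

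For 57 of the 150 genes named in the Results, the TCDD effect differed between the lines by edgeR's quasi-likelihood test of the difference. Of these, 41 were lower and 16 higher in mutants. Genes named only under the other observations, mmp13a among them, were not counted. The following log2 differences, mutants minus wild type, belong to genes called in both lines, up with TCDD in wild type and down in mutants: acvr1bb (-1.80), cacna1c (-4.29), cenpf (-1.30), crim1 (-3.25), CSRNP3 (-6.74), dcc (-2.43), egln2 (-2.92), ext1b (-6.05), fbn2b (-1.80), ism2a (-4.29), itchb (-5.50), itga9 (-2.26), kank2 (-5.37), kita (-1.76), mmp24 (-5.65), nfixb (-2.37), nyap2b (-1.49), palm2 (-6.06), PIEZO2 (1 of many) (-8.85), ptprdb (-2.19), ryr1b (-1.15), ryr3 (-1.21), sh3pxd2aa (-3.63), slc17a6a (-1.95), slc25a37 (-4.51), tbc1d9 (-4.70), tfe3a (-6.71), tgfbr1a (-2.62) and trhra (-5.04). The other lower differences were acanb (-2.43), ahr2 (-0.38), arnt2 (-0.47), clocka (-3.08), f5 (-0.76), hmcn2 (-5.44), man2a1 (-4.93), mri1 (-4.58), pax3a (-0.70), stab1 (-1.35), tgfbr1b (-5) and thrb (-0.50). The higher differences were apoc1 (0.63), apoea (0.92), apoeb (0.49), bfsp2 (0.37), cyp1a (0.89), cyp1c1 (0.54), epyc (0.33), gclc (0.41), gstp1 (0.53), hsp90aa1.2 (0.55), mfsd2ab (1.18), mt-atp6 (0.33), pck1 (1.08), pfkma (0.44), tiparp (0.51) and ugt1b1 (0.71).

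Libraries that stood apart from the others of their group were tested in both mutant groups, whose 4 libraries allow it. Of 300 tests of named genes, 18 had a library apart (6%), where chance gives about 5%, and 1 of 10 tests of library measures had one. In CPM, mutant DMSO replicate 1 was apart in ctsl.1 (0.290), replicate 2 in cryba1l1 (76.5) and foxq1a (4.21), replicate 3 in mef2ca (225), mhc1uba (0.0451), slc17a6a (17.3) and smyhc1 (16.0), and replicate 4 in tyrp1a (74.6). Mutant TCDD replicate 1 was apart in ldb2b (0.194), pdha1a (8.32) and ugt1ab (54.3), replicate 2 in ndufs7 (7.45), replicate 3 in dcc (6.30), kank2 (3.01), rpl13 (299) and tgfbr1b (3.43), and replicate 4 in pfkma (81.3) and tapt1b (0.427). Mutant DMSO replicate 2, the deepest library, also stood apart in genes detected (23679).

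The 2044 genes with a lower TCDD effect in mutants were weighed as a pattern. Across genes, weights on the within-group axis went with the difference at a Pearson r of -0.798, and with the library score as a term 0% of the 2044 stayed called and lower, their median going from -1.47 to -0.47 log2 while the median SE went from 0.297 to 0.326. The calls therefore ended because the estimates shrank, and 59.6% of the variance of the score itself follows the difference term, so that an axis shared with the libraries is a candidate explanation and removing it also removes part of any real difference. Unequal depth is argued against, since 96.4% stayed called with libraries thinned to the lowest total, and so are exchanged exposure labels, since the lowest cyp1a CPM with TCDD was 144 times the highest in DMSO. A difference between lines or dishes in state or stage, and gene length or GC content, remain open and untested.

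Other splits of the same libraries were fitted as well. Chance is argued against for TCDD in mutants (1 of 35 splits gave as many calls as the real 7253, highest other 293), for the mutation in DMSO (1 of 35, 3378, highest other 1401) and for the mutation in TCDD (1 of 35, 5552, highest other 1948). With 35 splits no lower share is possible, so chance is not excluded for them. For the difference of TCDD effects, 1 of 100 drawn splits gave as many calls as the real 2416 (highest other 2185). These splits redrew exposure labels within each line, so they test for no TCDD effect and not for equal effects in both lines. For the difference, chance is therefore neither argued against nor excluded. For TCDD in wild type the splits are too few for a share under 0.05 (1 of 10, real 2933, highest other 1).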

How the results depend on the processing

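The library score as a term and the joint omission of wild-type DMSO replicate 4 and mutant DMSO replicate 3 were alternatives chosen after seeing the data. Of the planned ones, named genes were followed only under RLE scaling, DESeq2, the replicate block, only the groups compared and each library left out. Under these, 2811 values of 240 named-gene results kept direction and side of the threshold, 37 lost the call and 7 gained it. A further 5 that were not called changed sign, and none that was called reversed. Counts of genes higher and lower are given in that order, and the cause was not tested except where fewer libraries were fitted. Fitting only the groups compared gave 773 and 397 for TCDD in wild type and 1003 higher for the mutation in DMSO. DESeq2 gave 1798 lower for TCDD in wild type and 832 higher for the difference, where no low-count filter gave 571 and a strict one 779. At least 2-fold were 730 and 66 (TCDD in wild type), 354 and 904 (TCDD in mutants), 610 and 584 (mutation in DMSO), 378 and 1646 (mutation in TCDD) and 46 higher (difference). Leaving out 1 library at a time gave 1177 to 1709 and 602 to 1308 for TCDD in wild type, 928 to 1877 and 1136 to 1595 for the mutation in DMSO, 1430 to 1859 higher for the mutation in TCDD and 132 to 609 higher for the difference. Lists called by camera fell to 1, 1, 0 and 0 in the pairwise comparisons with an estimated correlation, against 13 for TCDD in mutants and 16 for the mutation in TCDD by fry. For the mutation in DMSO at least 2-fold, the odds ratio on chromosome 1 was 1.29 and the enrichment was lost (Fisher's exact test, adjusted p = 0.468). For genes called under both exposures it was 1.81 (Fisher's exact test, adjusted p = 2.42e-04).

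The library score as a term gave 602 and 396, 947 and 1248, 819 and 1015, and 451 and 780 in the pairwise comparisons, and 0 and 0 for the difference (edgeR, 1407 genes at an unadjusted p under 0.05). With it, TCDD effects shared between lines numbered 423 in the same and 15 in opposite directions with a Pearson r of 0.117 (from -0.108), and those of the mutation 555 and 12 with 0.558. With it 59 named-gene calls were lost, CSRNP3 (0.073) and PIEZO2 (1 of many) (0.1745) reversed for TCDD in mutants, and wfikkn1 for the mutation in DMSO was -2.41 (edgeR adjusted p = 0.0606). Since the score itself carries group differences, these losses need not mean that the effects are not real. Without both libraries named at the start, 1076 genes were lower for the mutation in DMSO and 149 higher for the difference.

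With the replicate number as a block, edgeR called 1498 and 994, 3335 and 3520, 1324 and 1427, and 1792 and 2952 in the pairwise comparisons and 317 and 1901 for the difference. With it, the differences of cyp1c1 (0.54) and tiparp (0.51) and the mutation in TCDD for cyp1d1 (0.37) were not called (edgeR adjusted p = 0.0592, 0.064 and 0.0657). The numbers do not pair the samples: 4 of 19 same-numbered pairs had correlated deviations over 0.1, and 4 of 14 samples correlated best with their own number. Simulated 2-fold changes, in data without the within-group axis, were recovered in 73.1% to 83.6% of genes in the pairwise comparisons and 44.8% for the difference.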

Other observations

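The tests of summed rrm2 copies and of the genes nearest wfikkn1 were chosen only after the result was seen.

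Many genes outside the AHR battery changed with TCDD in the same direction in both lines, and these were chosen after their values were seen. Besides fgf7, the connective tissue growth factor gene ccn2b rose by 2.43 ± 0.14 in wild type and 2.57 ± 0.12 in mutants, the muscle-derived peptide gene ostn by 2.41 ± 0.29 and 2.86 ± 0.26, the collagenase gene mmp13a by 1.71 ± 0.25 and 2.86 ± 0.24, the adhesion gene ncam3 by 1.87 ± 0.12 and 1.86 ± 0.11 and the cytochrome b5 gene cyb5a by 1.53 ± 0.13 and 1.92 ± 0.12. Genes that fell in both lines included prl (-1.44 ± 0.29 and -1.37 ± 0.25), edn2 (-1.21 ± 0.19 and -1.18 ± 0.17), the Notch ligand gene dlc (-1.04 ± 0.18 and -1.12 ± 0.16), the chemokine gene cxcl12a (-0.98 ± 0.13 and -1.06 ± 0.11) and the hyaluronan synthase gene has2 (-0.95 ± 0.16 and -1.24 ± 0.14). All had edgeR adjusted p at or under 0.00565 in each line. Of them, the difference was called only for mmp13a (edgeR adjusted p = 0.0403), which rose more in mutants. For the others equal responses are not shown, since the test recovered 11.9% of simulated 1.5-fold differences.

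Genes over 8-fold apart between the lines under both exposures, 22 higher and 98 lower in mutants, may reflect blocks of haplotype that differ between the lines. Of the 120, 64 were placed on a chromosome, and they formed 12 neighbouring pairs, against a mean of 0.261 and a highest of 4 in 10000 permuted sets (permutation p = 1e-04, the smallest they can give). On chromosome 1, where wfikkn1 lies, 13 of them were found (odds ratio 5.72, Fisher's exact test, adjusted p = 7.14e-05), and tapt1b and ldb2b are neighbours there. Linkage to the edited locus is argued against as the cause of all the calls, since their odds ratio on that chromosome was 1.37 in DMSO and 1.04 with TCDD. For part of them it remains open. Of the 50 placed genes nearest wfikkn1, 38% were called for the mutation in DMSO, against 21% of the other 601 on that chromosome (odds ratio 2.31, Fisher's exact test, p = 0.00787). With TCDD these were 42% and 29.5% (odds ratio 1.73, Fisher's exact test, p = 0.0778). For calls of the same direction under both exposures the odds ratio was 3.05 (Fisher's exact test, p = 0.00239), and for the genes over 8-fold apart 8.18 (p = 0.00176). Calls for TCDD in wild type, within 1 line, were fewer among the nearest genes, 4% against 13.8% (odds ratio 0.26, Fisher's exact test, p = 0.0487). These p are unadjusted. Whether sequence differences change expression or only the assignment of reads was not tested.

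For rrm2, whether reads moved between near-identical copies remains open. From wild type to mutants in DMSO, ENSDARG00000020711 went from 14.59 to 185 CPM and ENSDARG00000078069 from 150.7 to 2.945, while their sum was 1.14 times as high. With TCDD they went from 29.19 to 184.2 CPM (6.31-fold) and from 93.39 to 1.891, while their sum was 1.52 times as high (1.3 times over both exposures). The 29.19 CPM in wild type had an SD of 21.6, so that the 6.31-fold is uncertain. Limits set after the values were seen, a sum within 1.5-fold and each ID over 8-fold apart, were met in DMSO and missed with TCDD.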
